A study of Danio rerio with 32 samples.

How the data were processed

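Messenger RNA was measured in the liver and skeletal muscle of adult female zebrafish of the AB strain that were wild type or carried a knockout of gys2, the gene for liver glycogen synthase. Per the labels, 8 fish of each genotype were taken, and livers and muscles were sequenced as 8 libraries per tissue and genotype, which gave 32 libraries in 4 groups of 8. The libraries were made by Lasy-Seq, a method that reads the 3′ end of polyadenylated transcripts. Per the labels' protocols, RNA was extracted directly in TRI reagent, reverse transcribed with a primer that carried the index of its sample, and all reverse-transcription products were pooled before the second strand was made. Replicates within a group are separate fish per the labels. With 8 fish of each genotype, liver and muscle can come from the same fish, but which liver goes with which muscle library is not given in the sources used here. Tests across the tissues treat the libraries as independent, and their errors would differ if the pairs were known. Also not given are dates, batches and the position of the lesion.

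The authors deposited whole-number counts per gene symbol, with 1 column per library and no normalization. The submitters' processing notes name fastp 0.23.4, BWA 0.7.17-r1188 and Salmon 1.10.2 and the genome build GRCz11, with no role or order. Whether the whole numbers are rounded Salmon estimates, which annotation release was counted, whether strand was used and whether molecular identifiers were read are not given in the sources used here. The reads are PCR products with no stated molecular identifier, so counting errors computed from them cover counting alone. The table held 31658 genes, of which 1430 were at 0 in each of the 32 libraries. Library totals ran from 1514099 to 15351773 counts. Genes are named by the symbols in the authors' table. Reads of near-identical copies, such as the vitellogenin genes, g6pca.1 and g6pca.2, hspa8 and its copy, and the trypsin genes, can be split between copies in ways the counts do not show, so single members of these families are uncertain.

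The sample groups, the tests, the gene lists, the rule for named genes and a set of processing alternatives were fixed before the data were examined. Differences between genotypes were tested within each tissue with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3 (robust fit, TMM scaling, genotype as the only term). Genes were filtered with filterByExpr at its defaults, a minimum count of 10 and a minimum total of 15. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. The difference of the genotype effect between liver and muscle was tested as an interaction term over all 32 libraries, and liver was compared with muscle over the 16 wild-type libraries. Abundances are given as CPM, counts scaled to the filtered library size times its TMM factor, as mean ± SD over 8 libraries, and log2 changes are given ± SE. For gys2 and gys1, and for library totals and shares of counts, the genotypes were also compared with two-sided exact permutation tests of 8 against 8 libraries, on log2(CPM + 0.5) for genes. The smallest p that such a test can give is 0.0001554. Genes private to liver had a median over 100 CPM of library totals in wild-type liver and over 32 times that in wild-type muscle. Genes private to muscle had a median over 100 CPM in wild-type muscle and over 16 times that in wild-type liver.

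A total of 50 gene lists with at least 3 tested members, covering carbohydrate, lipid and energy metabolism, protein turnover, stress, liver products and markers of other cell types, were tested with camera in limma 3.58.1. Camera compares the members of a list with all other genes; its preset correlation between genes of 0.01 was used, with a correlation estimated per list and the rotation test fry beside it. Counts of members are given at the adjusted p over all genes and adjusted over the list alone. The pattern that gathered ribosomal protein genes also took in rps6ka1 and rps19bp1, which are not ribosomal proteins. Besides gys2 and gys1, the genes named are those called with a mean of at least 5 CPM over the 16 libraries of a tissue and at least 7 of 8 knockout libraries beyond the wild-type median, up to 8 in each direction. They also include up to 4 members with the smallest p of each list described, members of the glycogen, glycolysis, gluconeogenesis and pentose phosphate lists, and the 6 genes with the smallest p for the interaction.

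Alternatives were the Wald test of DESeq2 1.42.0 at its defaults, limma-voom with sample quality weights, DESeq2 size factors or library totals in place of TMM, no filter or at least 50 counts in 8 libraries, removal of the vitellogenin genes, the library number as a block, a 2-fold minimum and each library of a tissue left out in turn. Further alternatives were chosen after seeing the data: counts thinned to the shallowest library, cyclic loess between libraries, an adjusted p under 0.10, and both muscle libraries numbered 6 left out. Other splits of the samples were drawn 100 times with a fixed seed. Replicate libraries were checked for duplication over 112 pairs within groups: 0 pairs held identical counts, and the chi-square per degree of freedom was 5.10 or more in each pair.

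The fits were tested on simulated counts with 200 changed genes, drawn from the means and library sizes of each comparison. In the liver comparison (9438 genes), 28 of 100 genes changed by 1 on the log2 scale and 96 of 100 changed by 2 were recovered; in muscle (12415 genes) these were 59 and 95, for the interaction (13725 genes) 14 and 56, and for liver against muscle (10648 genes) 44 and 92. With genes simulated independently, camera called 5 of 5 moved lists and 0 of 5 unmoved lists with either correlation in liver. Figures were drawn with matplotlib 3.10.9.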

Results

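Transcripts were counted at their 3′ ends in 8 livers and 8 muscle samples each of wild-type and gys2 knockout zebrafish. Of the glycogen synthases, gys2 encodes the liver form and gys1 the muscle form, and transcripts of both were counted in liver. Depth differed between the genotypes in liver. Wild-type livers had a mean of 1859740 ± 296908 counts (SD, n = 8; 1514099 to 2366219) and knockout livers 6573850 ± 4104040 (n = 8; 2562717 to 15351773), so that no wild-type liver was as deep as any knockout liver (ratio of means 3.53; exact permutation p = 0.0001554, the smallest such a test can give). Muscle libraries had means of 3931370 ± 1717700 in wild type and 2901980 ± 437304 in knockout (n = 8 each; exact permutation p = 0.113). When every liver and muscle library was thinned to the same total, wild-type livers held 12043 ± 889 genes with at least 5 counts and knockout livers 10082 ± 658 (n = 8 each; exact permutation p = 0.0003108), against 12537 ± 606 and 13000 ± 942 in muscle (exact permutation p = 0.254).

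**Figure D1:**
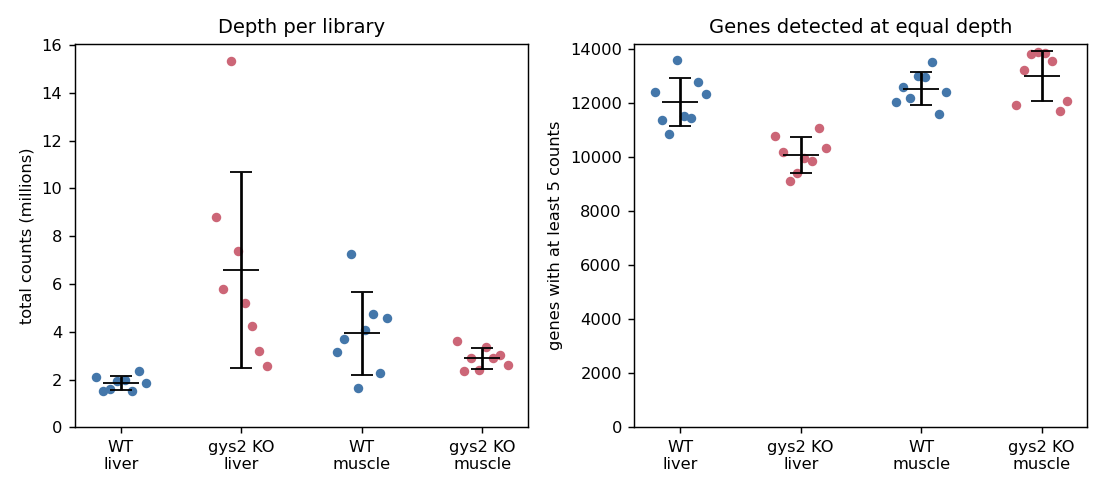
Total counts per library and the number of genes with at least 5 counts after thinning to equal depth, for the 8 libraries of each group, 1 point per library. Knockout livers have totals of 2562717 to 15351773, all above the wild-type livers, and at equal depth they hold a mean of 10082 genes against 12043 in wild type.

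The targeted gene was lower in knockout liver. Transcripts of gys2, the liver glycogen synthase, averaged 10.4 ± 6.30 CPM in wild-type liver and 1.08 ± 0.755 CPM in knockout liver (n = 8 each), a 9.67-fold lower mean. The difference of mean log2(CPM + 0.5) was -2.66 (exact permutation p = 0.0003108). Of the knockout livers, 7 of 8 lay below the lowest wild-type liver and all 8 below the wild-type median. These values rest on 6 to 37 counts per wild-type liver and 1 to 19 per knockout liver, and gys2 did not pass the count filter of the edgeR fit. In muscle gys2 stood at 0.946 ± 1.34 CPM in wild type and 1.32 ± 1.04 CPM in knockout (exact permutation p = 0.257), a level too low to show a difference at this depth. The labels do not say where the lesion lies, and a 3′ tag outside the altered part reports only the level of the transcript. The lower mean level in knockout liver goes with the genotype labels, but it does not show how the gene was changed.

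Transcripts of the muscle form gys1 had a higher mean than those of gys2 in wild-type liver (46.9 against 10.4 CPM). Like gys2, gys1 was lower in knockout liver. It averaged 46.9 ± 6.25 CPM in wild-type and 33.5 ± 4.17 CPM in knockout liver, and each of the 8 knockout livers lay below the lowest wild-type liver (difference of mean log2 values -0.48; exact permutation p = 0.0001554). In the edgeR fit over all liver genes its log2 change of -0.49 ± 0.16 did not pass adjustment (adjusted p = 0.122) and passed when adjusted over the list alone (adjusted p = 0.0462 among 10 glycogen synthesis genes). In muscle gys1 was at 188 ± 36.4 CPM in wild type and 161 ± 23.7 CPM in knockout (log2 change -0.22; edgeR adjusted p = 0.960, lower in 7 of 8 knockout libraries). Of 1000 genes of like abundance in liver, 12.8% had a change as low as that of gys1 or lower.

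**Figure D2:**
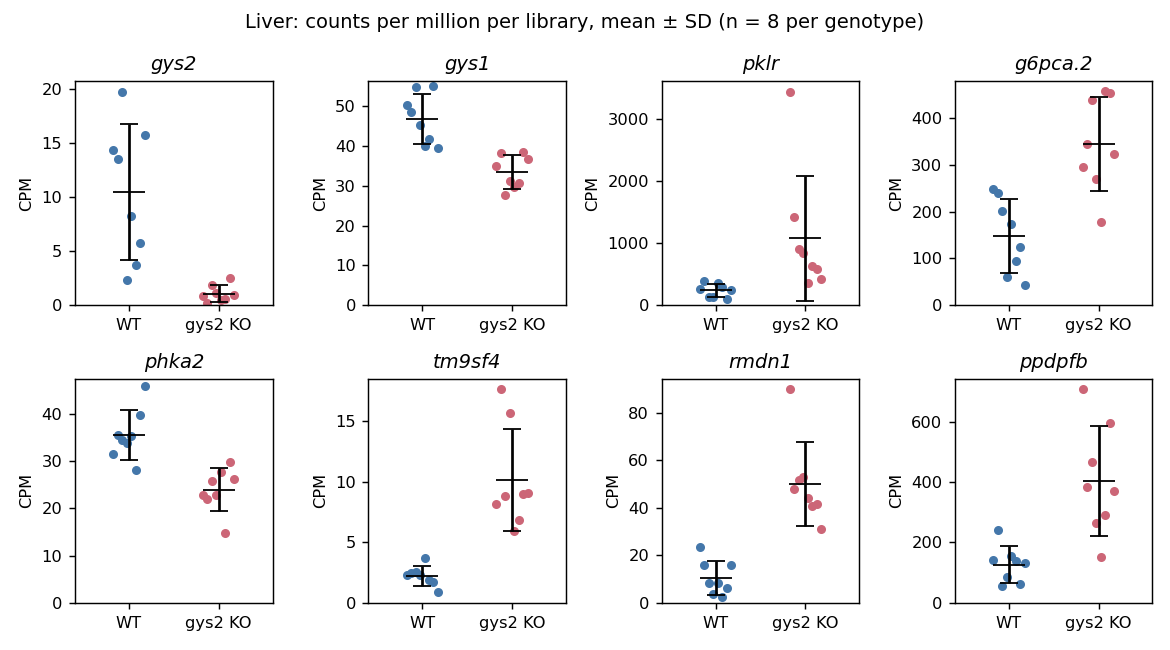
Abundance in CPM of gys2, gys1, pklr, g6pca.2, phka2, tm9sf4, rmdn1 and ppdpfb in each of the 8 wild-type and 8 knockout livers, with the mean and SD. For gys2 the means are 10.4 and 1.08 CPM, and for rmdn1 10.5 and 49.98 CPM, in wild type and knockout.

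The comparison of knockout with wild-type liver asked which liver transcripts follow the loss of the liver synthase. Genes that rose were tm9sf4, a membrane protein of the endosomal and Golgi system, from 2.23 ± 0.796 to 10.14 ± 4.21 CPM, and rmdn1, a regulator of microtubule dynamics, from 10.5 ± 7.20 to 49.98 ± 17.6 CPM (n = 8 each). Others that rose were the clone-named gene si:ch1073-416d2.3 (log2 change 1.598), the tight-junction gene cldn2 (16.1 ± 4.32 to 34.8 ± 9.68 CPM), ppdpfb, named for pancreatic progenitor differentiation (127 ± 60.097 to 404 ± 182 CPM), and the opsin-family gene rgrb (18.5 ± 8.96 to 41.3 ± 8.53 CPM). The clone-named gene CU657925.1 fell from 7.97 ± 2.28 to 2.86 ± 1.21 CPM. In the edgeR fit these were the 7 called of 9438 genes tested, 6 higher and 1 lower, each with 8 of 8 knockout livers beyond the wild-type median. Log2 changes of the risers ran from 1.11 ± 0.21 (cldn2, adjusted p = 0.0371) to 2.25 ± 0.34 (rmdn1, adjusted p = 0.00582), with adjusted p = 0.00378 for tm9sf4, whose change was 2.19 ± 0.32, and CU657925.1 changed by -1.49 ± 0.29 (adjusted p = 0.0461). At an unadjusted p under 0.05 there were 2111 genes, 970 higher and 1141 lower, where 471.9 are expected by chance, and at an adjusted p under 0.10 there were 216, 111 higher and 105 lower.

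The liver count depended on the tool, the scaling, the filter and single libraries. DESeq2 called 423 genes (262 higher, 161 lower) and limma-voom with quality weights 215 (111 higher, 104 lower), and these included 5 and 7 of the 7 genes. With library totals in place of TMM edgeR called 3249 genes, 16 higher and 3233 lower, around a median of all genes of -0.54. Without a filter it called 99 (96 higher, 3 lower) and with at least 50 counts in 8 libraries 48 (21 higher, 27 lower). Leaving out each library in turn gave 2 to 68 calls. There were 68 without wild-type liver 5, 33 without wild-type liver 2 and 12 without wild-type liver 3, and 13 and 11 without knockout livers 8 and 1. There were 4 without knockout liver 2, 3 without knockout liver 7 or wild-type liver 4 or 6, and 2 without knockout liver 4 or 6 or wild-type liver 1 or 7. In all 16 of these fits tm9sf4 and rmdn1 were called, cldn2 and si:ch1073-416d2.3 in 9, ppdpfb in 6, rgrb in 5 and CU657925.1 in 3. Under the alternative fits that keep all livers, rmdn1 was tested in 10 and passed in 10, and tm9sf4 was tested in 8 and passed in 7. The values of tm9sf4 rest on a few counts per wild-type liver. With all libraries thinned to the shallowest 1 gene was called, rmdn1, in the draw counted among these fits. Over 10 such draws 0 to 4 genes were called. In draws 4 and 10 there were 0 calls, so neither rmdn1 nor tm9sf4 passed there.

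The series names glucose metabolism in the liver as its subject, and the lists of glucose pathways bear on it. List results are from camera at its preset correlation, and with a correlation estimated per list 0 of the 50 lists passed in liver (smallest adjusted p = 0.556). Of 26 glycolysis genes, 15 had a positive and 11 a negative log2 change (median 0.25, camera adjusted p = 0.0851). The liver pyruvate kinase pklr, which catalyses the last step of glycolysis, stood at 238 ± 106 CPM in wild type and 1074 ± 1010 CPM in knockout, above the wild-type median in 8 of 8 livers. Its log2 change of 2.18 ± 0.44 did not pass the edgeR adjustment over all genes (adjusted p = 0.0621) and passed when adjusted over the list alone (adjusted p = 0.00256), as 1 of the 26 genes. With each liver library left out in turn, pklr had log2 changes of 1.69 to 2.37 and edgeR adjusted p from 0.0348 to 0.140, and it passed over all genes in 5 of the 16 fits (without knockout liver 1, 5 or 8 or wild-type liver 2 or 5). The triosephosphate isomerase tpi1b had 79.4 ± 41.6 and 135 ± 58.7 CPM, pgk1 62.6 ± 21.9 and 94.7 ± 32.9 CPM and gapdh 1166 ± 428 and 1688 ± 500 CPM. These 3 lay above the wild-type median in 8 of 8 knockout livers and did not pass either adjustment. Glucokinase, gck, which traps glucose in hepatocytes, varied widely within both genotypes (172 ± 195 and 235 ± 225 CPM; log2 change 0.45 ± 0.91, edgeR adjusted p = 0.782, and -0.08 when scaled to library totals).

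The gluconeogenesis list was higher in knockout liver: 8 of 9 tested genes had a positive change, with a median of 0.67 (camera adjusted p = 0.0147). The list no longer passed without knockout liver 1 (adjusted p = 0.0539), with at least 50 counts in 8 libraries (0.134) or with cyclic loess (0.0519). The glucose-6-phosphatase g6pca.2, which releases free glucose, went from 148 ± 79.4 to 345 ± 99.6 CPM and was the 1 member called when adjusted over the list alone, against 0 over all genes. Its log2 change was 1.22 ± 0.32, in 8 of 8 livers (edgeR adjusted p = 0.0859 over all genes and 0.00642 over the list). Its near copy g6pca.1 had 11.99 ± 9.47 and 30.2 ± 22.2 CPM, and reads can be split between both. The fructose-bisphosphatase fbp1b had 366 ± 234 and 581 ± 299 CPM and the phosphoenolpyruvate carboxykinase pck1 104 ± 126 and 197 ± 162 CPM. The glucose-6-phosphate transporter slc37a4b was the negative member, at 38.4 ± 12.7 and 27.7 ± 6.08 CPM.

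Glycogen breakdown genes went both ways in knockout liver. Of 10 tested members, 5 were positive and 5 negative (median -0.07, camera adjusted p = 0.620), and 3 fell when adjusted over the list alone, against 0 over all genes. These were the phosphorylase kinase subunits phka2 (35.6 ± 5.36 to 24.01 ± 4.58 CPM; log2 change -0.57 ± 0.17, edgeR adjusted p = 0.102 over all genes and 0.0272 over the list) and phkg1a (72.3 ± 22.7 to 48.1 ± 7.42 CPM; 0.0378 over the list), each lower in 8 of 8 livers, and the debranching enzyme aglb (16.3 ± 4.17 to 10.2 ± 5.11 CPM; 0.0495 over the list), lower in 7 of 8. The liver phosphorylase pygl, which these enzymes serve, had 161 ± 66.6 and 236 ± 129 CPM (log2 change 0.56 ± 0.30). Of 10 glycogen synthesis genes, 6 were positive and 4 negative (median 0.13, camera adjusted p = 0.936), and gys1 was the 1 member that fell when adjusted over the list alone. The branching enzyme gbe1a had 9.43 ± 3.55 and 6.16 ± 1.97 CPM and the phosphatase-targeting subunit ppp1r3b 9.79 ± 4.87 and 17.5 ± 10.4 CPM.

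In the pentose phosphate pathway, which makes NADPH, 7 of 9 genes were positive (median 0.42, camera adjusted p = 0.104), and 0 were called by edgeR over all genes or adjusted over the list alone, with 3 at an unadjusted p under 0.05. The means of pgd (28.5 ± 21.8 and 145 ± 233 CPM) and tktb (80.2 ± 39.9 and 285 ± 355 CPM) differed less than the knockout livers did among themselves; 5 and 6 of 8 knockout livers lay above the wild-type median. Without knockout liver 1 the log2 change of pgd went from 2.35 to 1.36 and that of tktb from 1.83 to 1.18. Among 13 genes of glucose and fructose entry (median 0.33, camera adjusted p = 0.766), the triokinase tkfc, an enzyme of fructose use, rose when adjusted over the list alone, from 11.5 ± 4.59 to 26.5 ± 13.3 CPM (log2 change 1.21 ± 0.31, 7 of 8 livers; edgeR adjusted p = 0.0859 over all genes and 0.00753 over the list). The glucose transporter slc2a2 had 86.6 ± 38.8 and 135 ± 44.4 CPM (0.0847 over the list).

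Downstream of pyruvate, 26 of 29 pyruvate dehydrogenase and TCA cycle genes were positive in knockout liver (median 0.42, camera adjusted p = 9.06e-06), and 6 rose when adjusted over the list alone, against 0 over all genes. Among these were pdha1a, a subunit of pyruvate dehydrogenase (20.0 ± 4.64 to 36.2 ± 13.7 CPM, 8 of 8 livers), and dldh, the dihydrolipoamide dehydrogenase shared by this complex and the TCA cycle (38.0 ± 9.36 to 62.6 ± 15.7 CPM, 7 of 8 livers), with edgeR adjusted p = 0.0148 and 0.0240 over the list. Nuclear genes of oxidative phosphorylation were positive in 84 of 86 cases (median 0.46, camera adjusted p = 6.44e-12), and 3 rose when adjusted over the list alone, among them the cytochrome oxidase subunit cox5ab (37.1 ± 12.5 to 69.2 ± 15.7 CPM, 8 of 8 livers; 0.0282 over the list). Of 13 mitochondrially encoded genes 11 were positive (median 0.51, camera adjusted p = 0.000531); adjusted over the list alone 9 rose and 1 fell. With cyclic loess this list turned to a negative sign in camera and did not pass (adjusted p = 0.998). The complex I gene mt-nd6 went from 509 ± 200 to 936 ± 133 CPM and mt-nd4l from 166 ± 145 to 59.3 ± 20.3 CPM, each in 8 of 8 livers (0.00256 over the list for both).

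Lists of lipid metabolism differed in their medians. All 23 cholesterol synthesis genes had a positive change, with a median of 1.24 (camera adjusted p = 0.000505), although 0 were called by edgeR over all genes or adjusted over the list alone and 5 had an unadjusted p under 0.05. The regulator srebf2 had 8.77 ± 4.07 and 15.7 ± 6.62 CPM and the reductase dhcr7 89.6 ± 15.4 and 140 ± 53.9 CPM. Of 12 fatty acid synthesis genes 6 were positive and 6 negative (median 0.46, camera adjusted p = 0.652). The desaturase fads2 rose when adjusted over the list alone, from 617 ± 233 to 1381 ± 471 CPM (log2 change 1.16 ± 0.25, 8 of 8 livers; edgeR adjusted p = 0.05998 over all genes and 0.00103 over the list), and with each library left out in turn it passed over all genes in 3 of 16 fits (without wild-type liver 2, 3 or 5). The fatty acid synthase fasn had 94.7 ± 64.6 and 579 ± 909 CPM, above the wild-type median in 5 of 8 knockout livers, and its log2 change of 2.61 was 1.83 without knockout liver 1. Fatty acid oxidation genes were positive in 29 of 33 cases (median 0.39, camera adjusted p = 0.000211), and apolipoprotein genes in 13 of 18 (median 0.37, camera adjusted p = 0.00318, or 0.446 with cyclic loess).

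Lists of genes for making and clearing protein had positive medians in knockout liver. Against random lists of like abundance the median of the proteasome list lay at percentile 100 and that of the ribosomal list at 65.4. Of 44 proteasome genes 39 were positive (median 0.81, camera adjusted p = 5.72e-08), and 6 rose when adjusted over the list alone, among them psmc3 (48.0 ± 13.6 to 85.9 ± 21.5 CPM) and psmb1 (18.3 ± 6.48 to 39.5 ± 25.5 CPM), each in 7 of 8 livers (edgeR adjusted p = 0.0181 and 0.0316 over the list). Ribosomal protein genes were positive in 84 of 85 cases (median 0.46, camera adjusted p = 1.06e-13), with rpl7a, from 1555 ± 347 to 2850 ± 804 CPM, called when adjusted over the list alone (0.0239, 7 of 8 livers), and over all genes in 2 of the 16 fits that leave out a library (knockout liver 1 or wild-type liver 2). With cyclic loess the ribosomal list turned to a negative sign in camera and did not pass (adjusted p = 0.111). Plasma protein genes of hepatocytes were positive in 29 of 30 cases (median 0.46, camera adjusted p = 1.79e-06, or 0.176 with cyclic loess). The vitellogenesis list, the egg-yolk precursors that the liver of laying females secretes, was positive in 8 of 9 cases (median 0.61, camera adjusted p = 0.0173). It did not pass with cyclic loess (adjusted p = 0.964) or with at least 50 counts in 8 libraries (0.0526). Its gene vtg1 had 122180 ± 41105 and 259955 ± 128596 CPM, or 14.1 ± 4.34% and 20.1 ± 8.42% of the counts (exact permutation p = 0.0931). The log2 change of vtg1 ran from 0.10 to 1.26 over 9 alternative settings. All vitellogenin genes held 24.2 ± 7.86% of the counts in wild-type and 30.3 ± 12.1% in knockout livers (exact permutation p = 0.249).

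Markers of other cell types moved beside these groups. Digestive enzymes of the exocrine pancreas, which lies close to the liver and intestine, were positive in 20 of 21 cases (median 0.81, camera adjusted p = 0.00131), and edgeR called 0 of them over all genes, adjusted over the list alone or at an unadjusted p under 0.05. Macrophage genes were positive in 14 of 18 cases (median 0.36, camera adjusted p = 0.00771), with the complement gene c1qc called over the list alone (7.65 ± 2.73 to 14.9 ± 6.20 CPM, 8 of 8 livers; edgeR adjusted p = 0.0301). Erythrocyte genes were positive in 8 of 11 cases (median 0.60, camera adjusted p = 0.0376; adjusted p = 0.0580 without knockout liver 1), with the globin hbba1 at 331 ± 197 and 558 ± 194 CPM. Nerve and glia genes were negative in 19 of 21 cases (median -0.36, camera adjusted p = 0.00569) and regulators of muscle formation in 12 of 12 (median -0.37, camera adjusted p = 0.00522). With counts thinned to the shallowest library neither macrophage (adjusted p = 0.197) nor nerve and glia genes (0.109) passed, nor did they with at least 50 counts in 8 libraries (0.161 and 0.0570). Erythrocyte genes did not pass with the latter filter (0.0743) or with cyclic loess (0.0774). Examples of the lower nerve and muscle-regulator genes were syn2a (9.48 ± 5.31 and 5.38 ± 0.884 CPM) and mef2cb (30.9 ± 11.3 and 20.2 ± 3.61 CPM). Genes private to muscle held 0.764 ± 0.0811% of the counts in wild-type and 0.563 ± 0.0615% in knockout livers (exact permutation p = 0.0001554). On library totals their median log2 change was -0.50, near the -0.54 of all tested liver genes, so relative to other genes they moved little. Liver and muscle samples were pooled before the second strand was made, and wild-type livers were shallower. The share of genes private to muscle and the levels of muscle regulators in liver therefore include any signal carried over from muscle libraries.

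Of the 50 lists, 22 passed camera at the preset correlation in liver, 20 higher and 2 lower, and 0 passed with an estimated correlation. The estimates had a median of 0.177 and reached 0.840 for the ribosomal genes. Fry, which asks whether a list moves on balance 1 way, called 0 (smallest adjusted p = 0.0604), and its test for change in either direction called 11. List directions are relative to all genes: scaling to library totals alone put the median of all genes at -0.54 and turned the sign of 11 of the 22 list medians, and 0 of 22 relative to that shift. These 11 were ribosomal proteins, nuclear oxidative phosphorylation, TCA cycle, fatty acid oxidation, amino acid catabolism, autophagy, apolipoproteins, macrophages, acute phase, cytochrome P450 and heat shock. Abundance went along with the change: the median log2 change was -0.10 among 2359 genes under 3 in mean log2 CPM and 0.45 among 501 genes over 7. For 8 of the 22 lists, ribosomal, plasma protein and mitochondrially encoded genes among them, the median lay within the central 95% of lists of like abundance.

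**Figure D3:**
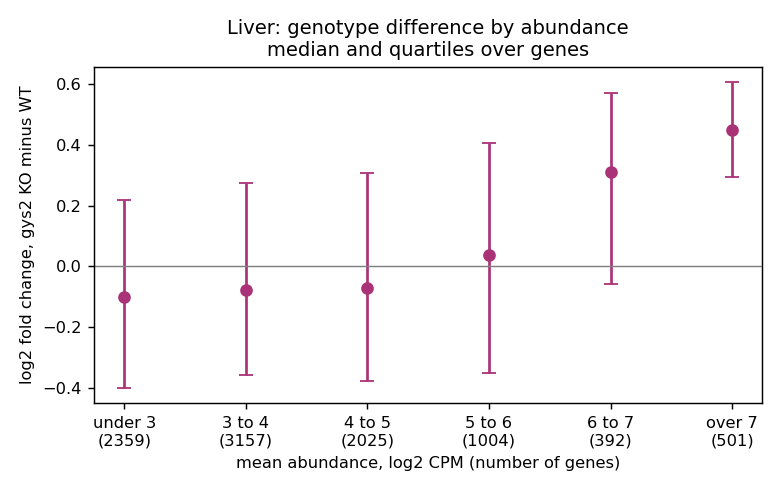
Log2 change of knockout over wild-type liver by mean abundance in log2 CPM; points are medians and bars quartiles over the genes of each abundance class, with their number. The median goes from -0.10 in the lowest class (2359 genes) to 0.45 in the highest (501 genes).

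**Figure D4:**
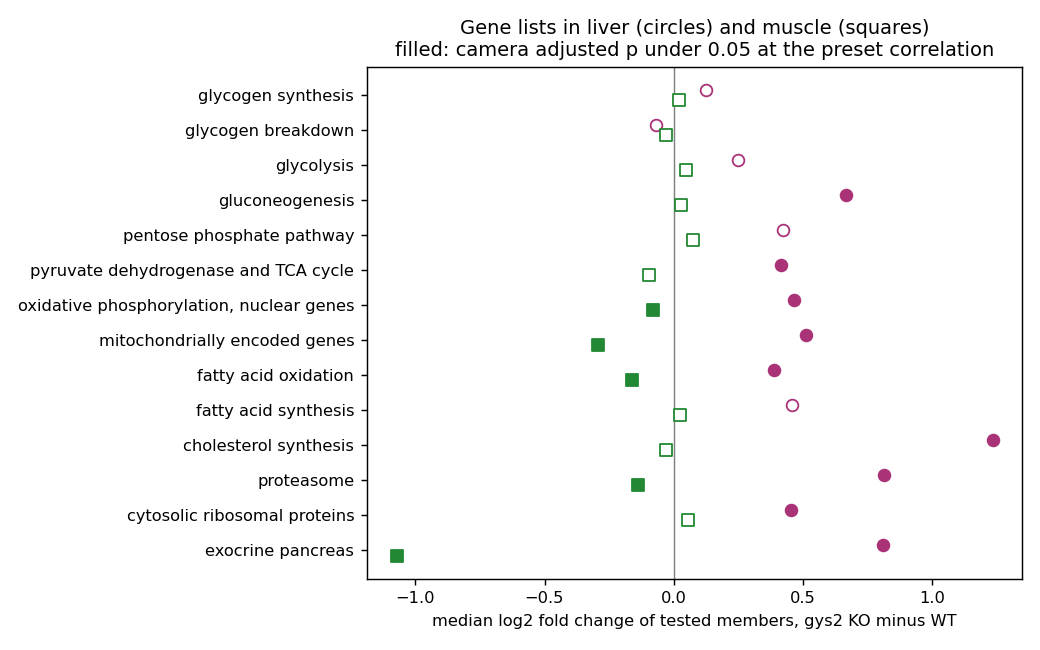
Median log2 change of the tested members of 14 gene lists, knockout minus wild type, in liver (circles) and muscle (squares); filled symbols passed camera at the preset correlation. Cholesterol synthesis is at 1.24 and the proteasome at 0.81 in liver, the exocrine pancreas is at 0.81 in liver and -1.07 in muscle, and 11 of the 22 liver medians that passed turn negative when scaled to library totals alone.

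In muscle the comparison asked whether loss of the liver synthase is followed by changes in a tissue with few gys2 transcripts. The lowest p belonged to the carboxypeptidase gene cpa5, at 10.3 ± 9.14 CPM in wild type and 1.71 ± 1.58 CPM in knockout (n = 8 each; log2 change -2.50 ± 0.50, 8 of 8 libraries lower). Both the exocrine pancreas list and the neutrophil list hold cpa5, so it does not name a cell type. Its edgeR adjusted p = 0.437 did not pass. edgeR called 0 of 12415 genes, with 588 at an unadjusted p under 0.05 (251 higher, 337 lower; 620.75 expected by chance). DESeq2 called 2 genes, 1 higher and 1 lower, and limma-voom with quality weights 0, with 1175 and 1192 genes at an unadjusted p under 0.05. Without knockout muscle 6 edgeR called 1 gene, cpa5, which also passed with DESeq2 (adjusted p = 0.0114) and in edgeR without a filter (0.00178), with log2 changes of -2.54 and -2.51. With the library number as a block edgeR called 2 genes, both lower, cpa5 among them, and 907 had an unadjusted p under 0.05. Simulated changes of 1 on the log2 scale were recovered for 59 of 100 genes at this depth.

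Digestive enzymes of the pancreas stood lower in knockout muscle, where 8 of 10 were negative (median -1.07, camera adjusted p = 1.87e-05), and 4 fell when adjusted over the list alone, against 0 over all genes. Besides cpa5, which the neutrophil list also holds, these were ctrb1 (10.5 ± 7.03 to 4.48 ± 2.62 CPM), prss59.2 (11.3 ± 8.98 to 4.32 ± 2.92 CPM) and prss1 (11.6 ± 8.84 to 4.45 ± 3.89 CPM), each lower in 7 of 8 libraries (edgeR adjusted p = 0.0118, 0.0248 and 0.0489 over the list). The gene prss1 held means of 0.00110% and 0.000479% of the counts in wild-type and knockout muscle, against 0.00780% and 0.0119% in liver. Whether these transcripts, cpa5 included, came from other tissue, other cell types or other libraries was not tested. They are therefore not read as a change within muscle cells. Mitochondrially encoded genes were negative in 11 of 13 cases (median -0.29, camera adjusted p = 6.57e-05), fatty acid oxidation in 28 of 33 (median -0.16; 0.000914), the proteasome in 33 of 45 (median -0.14; 0.0136), nuclear oxidative phosphorylation in 68 of 86 (median -0.08; 0.0227, and 0.133 when scaled to library totals) and acute phase genes in 24 of 27 (median -0.30; 0.0376). In these 5 lists 0 members were called, and with an estimated correlation 0 of the 50 lists passed in muscle (adjusted p = 0.954 for each of the 6). With counts thinned to the shallowest library the digestive enzymes (adjusted p = 0.199), the proteasome (0.0714) and the acute phase genes (0.157) did not pass, and with at least 50 counts in 8 libraries the digestive enzymes were too few to test. Acute phase genes are made by the liver. Genes private to liver held 6.84% of the counts in wild-type muscle 6 and 3.55% in knockout muscle 6, against 0.590 to 0.921% and 0.626 to 0.852% in the other 7 libraries of each genotype, and without these libraries the acute phase list had a camera adjusted p of 0.297. Scaling to library totals put the median of all muscle genes at 0.13. It turned the median of nuclear oxidative phosphorylation to 0.02 and left those of the proteasome at -0.00 and fatty acid oxidation at -0.05, while relative to that shift 0 of the 6 medians turned.

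Glucose pathways in knockout muscle had median changes of 0.05 for 28 glycolysis genes, 0.03 for 10 gluconeogenesis genes, 0.07 for 8 pentose phosphate genes, -0.03 for 11 glycogen breakdown genes and 0.02 for 14 glycogen synthesis genes, the last with a negative sign in camera. Camera gave them adjusted p from 0.644 to 0.818, and edgeR called 0 members over all genes or adjusted over the list alone. The phosphorylase kinase subunit phkb had 40.21 ± 9.61 CPM in wild type and 27.3 ± 6.51 CPM in knockout (log2 change -0.56, 8 of 8 libraries lower; 0.0503 over the list). The glycolytic gene gapdh had 11385 ± 3093 and 8910 ± 2803 CPM, and decr2, an enzyme of fatty acid oxidation, 7.92 ± 3.90 and 4.098 ± 1.56 CPM.

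The interaction test asked which genotype effects differed between the tissues. The genes with the smallest p had a positive change in liver and a negative one in muscle. They were smim8, a small membrane protein (log2 change 0.98 in liver and -0.63 in muscle), ppdpfb (1.67 and -0.32), the mitochondrial translocator tspo (0.65 and -0.70), the complex I gene mt-nd3 (0.81 and -0.50), the pyruvate dehydrogenase gene pdha1a (0.87 and -0.38) and the membrane protein gene TMEM19 (0.65 and -0.66). The difference was estimated in a joint fit of all 32 libraries with its own scaling, in which the median over all genes was 0.11, and is not the gap between the values of the tissue fits. It was 2.14 ± 0.38 for ppdpfb and 1.78 ± 0.31 for smim8 (edgeR adjusted p = 0.00901 for both). The difference was 1.51 ± 0.28 for tspo (adjusted p = 0.0147), 1.46 ± 0.28 for mt-nd3 (adjusted p = 0.0199), 1.44 ± 0.29 for pdha1a (adjusted p = 0.0294) and 1.48 ± 0.30 for TMEM19 (adjusted p = 0.0298). In liver 8 of 8 knockout libraries lay above the wild-type median for each of these except TMEM19 (7 of 8), and in muscle 5 of 8 (ppdpfb), 7 of 8 (smim8, mt-nd3, pdha1a) or 8 of 8 (tspo, TMEM19) lay below it. edgeR called 29 of 13725 genes, 26 with a more positive and 3 with a more negative effect in liver, and 2507 had an unadjusted p under 0.05 (686.25 expected). Without both muscle libraries numbered 6 the count was 7, of which 6 were among the 29, and with counts thinned to the shallowest library it was 3. With the library number as a block it was 8, of which 6 were among the 29. The ratio of mean depth, knockout over wild type, was 3.53 in liver and 0.738 in muscle. An effect of depth is therefore not separated from a genotype effect that differs between the tissues. DESeq2 called 165 and limma-voom 517. With library totals the balance turned, with 22 more positive and 3350 more negative in liver around a median of all genes of -0.70. The difference of the gene lists between tissues was not tested.

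Wild-type liver and muscle differed in the levels of members of the glycogen and glucose families. The synthase gys1 was lower in liver (172 ± 33.6 CPM in muscle and 59.0 ± 7.98 CPM in liver, n = 8 each; log2 difference -1.55), and the phosphorylases divided into pygl in liver (8.44 and 206 CPM; 4.56) and pygma in muscle (140 and 5.13 CPM; -4.79). Liver had more gck (13.9 and 221 CPM; 3.98) and pklr (14.4 and 304 CPM; 4.36), and muscle more of the kinase pkmb (1645 and 98.3 CPM; -4.07) and the aldolase aldoaa (5498 and 188 CPM; -4.87). Among gluconeogenesis genes fbp1b (18.1 and 473 CPM; 4.67), pck1 (3.22 and 138 CPM; 5.37) and g6pca.2 (23.005 and 189 CPM; 3.03) were higher in liver, and the muscle bisphosphatase fbp2 (50.03 and 1.45 CPM; -4.91) was higher in muscle. Each of these genes had 8 of 8 liver libraries on the stated side of the muscle median, and edgeR adjusted p was from 5.5e-17 (aldoaa) to 0.00101 (gck). Of the tested members, 1 of 12 glycogen synthesis genes was higher in liver and 6 in muscle, 1 and 5 of 10 for glycogen breakdown, 7 and 16 of 28 for glycolysis and 6 and 2 of 9 for gluconeogenesis. edgeR called 3607 of 10648 genes, 1596 higher in liver and 2011 higher in muscle. Scaled with DESeq2 size factors these were 1700 and 1901, and scaled to library totals 1306 and 2267. Signal from the other tissue, including the liver transcripts of wild-type muscle 6 (6.84% of its counts in genes private to liver), is not separated from expression in the lower values. Genes private to liver stood at 0.955 to 3.08% of their liver level in wild-type muscle and genes private to muscle at 1.21 to 6.12% of their muscle level in wild-type liver, ranges whose upper ends are set by how these genes were chosen. The lower values of pygma, aldoaa, pkmb, fbp2 and pck1 lie within these ranges and those of pygl, fbp1b and pklr not far above them, so these log2 differences are not exact.

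Among 9026 genes tested in both tissues edgeR called 3 in liver (2 higher, 1 lower), 0 in muscle and so 0 in both. DESeq2 calls also shared 0 genes. Across genes, which are not independent replicates, the log2 changes of the tissues had a Pearson r of -0.29 and a Spearman rho of -0.33. Mean depth of knockout over wild type was 3.53 in liver and 0.738 in muscle, so an effect of depth on this correlation is not excluded.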

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

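The tests of where the liver transcripts in the muscle samples came from were chosen after the result was seen. The counts over other splits of the samples were planned. Within groups of 8, a library is given here where its gap to the nearest of the other 7, over the range of the group, was above the 95% critical value of Dixon's test. That held in 14 of 144 groups, where chance alone gives about 1 in 20, or 7.2 groups.

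In both muscle libraries numbered 6, which held liver transcripts, genes private to liver took 6.84% of the counts in wild-type muscle 6 (other 7: 0.590 to 0.921%) and 3.55% in knockout muscle 6 (other 7: 0.626 to 0.852%), and the vitellogenin genes 5.27% (0.445 to 0.687%) and 2.74% (0.474 to 0.638%). Liver tissue or liver RNA in the muscle sample is a candidate explanation: of 99 genes private to liver, 99 in the wild-type and 94 in the knockout library lay above all other muscle libraries of their genotype, at least 94.9% in both. These are the genes whose summed share flagged the libraries, so the count shows only that the excess was not confined to a few genes. It does not separate liver in the sample from signal carried over from liver libraries after pooling. For wild-type muscle 6 the liver of its own number is argued against, since it matched best in 0% of 1000 resamples of the genes (r across genes 0.02). For knockout muscle 6 the liver of its own number matched best in 26.7% (r 0.29), too few to decide, so it cannot be told apart from another liver (best match of both, wild-type liver 7, r 0.52 and 0.38). No biological explanation was tested, and leaving both libraries out took the interaction calls from 29 to 7.

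Shares and genes with a library standing apart in muscle and liver were these. Genes private to muscle held 38.2% of the counts in knockout muscle 7 (other 7: 25.04 to 29.998%) and 0.946% in wild-type liver 4 (0.686 to 0.782%). The opsin-family gene rgrb stood at 39.2 CPM in wild-type liver 8 (11.0 to 19.3 CPM) and the glycolytic kinase pgk1 at 174 CPM in knockout liver 1 (70.28 to 91.6 CPM). Knockout liver 6 had 14.9 CPM of phka2 (21.9 to 29.8 CPM), and wild-type liver 1 had 3.89 CPM of tkfc (9.66 to 19.8 CPM). The proteasome gene psmc3 was at 40.11 CPM in knockout liver 7 (69.8 to 109 CPM) and dldh at 19.6 CPM in wild-type liver 4 (33.1 to 52.3 CPM). For the mitochondrial genes, mt-nd6 was at 976 CPM in wild-type liver 5 (315 to 514 CPM) and mt-nd4l at 107 CPM in knockout liver 5 (42.7 to 60.7 CPM).

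Genotype effects that differed between the tissues numbered 29 in the edgeR interaction test. Among the genes named here the liver effect minus the muscle effect was 2.37 ± 0.52 for rmdn1, 2.295 ± 0.51 for cldn2 and 1.33 ± 0.29 for mt-nd6 (edgeR adjusted p = 0.0390 for each, with 8 of 8 knockout livers above the wild-type median). It was 2.14 ± 0.38 for ppdpfb, 1.78 ± 0.31 for smim8, 1.51 ± 0.28 for tspo, 1.48 ± 0.30 for TMEM19, 1.46 ± 0.28 for mt-nd3 and 1.44 ± 0.29 for pdha1a. Of the 6 genes called higher in liver, 2 were tested in both tissues, ppdpfb among them. So rmdn1 and cldn2 cannot both have passed the count filter in muscle. For a gene under that filter the difference rests on low muscle counts.

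Among 100 splits of the 16 livers into 2 groups of 8, the real one included, 2 gave at least the 7 calls of the real one. That is a share under 0.05 of the splits drawn, which argues against chance but cannot exclude it. Splits of this kind do not separate genotype from depth in liver. The highest other split gave 222 calls, several times the real count, which points to a structure of the samples beside genotype, the nature of which was not tested. In muscle the real split gave 0 calls, which all 100 splits equal or exceed whatever the data (highest other 50), so this count says nothing about chance. For the interaction 1 of 100 splits, the real one, gave 29 calls or more (highest other 22), and for wild-type liver against muscle 1 of 100, the real one, gave 3607 or more (highest other 81). Chance alone is argued against for both, at a share under 0.05 of the splits drawn.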

How the results depend on the processing

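Chosen after seeing the data were the thinned counts, cyclic loess, the adjusted p under 0.10, the libraries left out for muscle 6, the list settings other than the estimated correlation, block and size factors, and the edgeR fit without a filter and the DESeq2 test of gys2; the other settings were planned. The planned limma-trend fit was not run because the values are whole.

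For gys2 the change in liver was -3.22 to -2.30 on the log2 scale and past the threshold wherever a test was made, DESeq2 giving no adjusted p, and in muscle gys2 passed under none of the settings run. Liver calls, 7 as reported (6 higher, 1 lower), became 423 with DESeq2 (262 higher, 161 lower), 215 with limma-voom and quality weights (111 and 104), 3249 with library totals (16 and 3233), 99 without a filter (96 and 3) and 48 with at least 50 counts in 8 libraries (21 and 27, with 3589 genes tested). They became 1 with thinned counts (0 to 4 over 10 draws), 13 with cyclic loess (10 and 3) and 216 at an adjusted p under 0.10. Library totals moved the median log2 change of all genes to -0.54, which accounts for the calls being nearly all lower; the cause of the other differences was not tested. Size factors gave 5, removal of the vitellogenin genes 7 and a 2-fold minimum 7. Leaving out 1 library gave 2 to 68 calls. Without wild-type liver 5 there were 68, wild-type 2 33, knockout 8 13, wild-type 3 12 and knockout 1 11. There were 4 without knockout 2, 3 without knockout 7, wild-type 4 or wild-type 6, and 2 without knockout 4, knockout 6, wild-type 1 or wild-type 7.

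Muscle calls, 0 as reported, became 2 with DESeq2, 3 without a filter and 0 to 1 when 1 library was left out (1 without knockout muscle 6, cpa5), and were 0 under the other settings without a block. Unadjusted p under 0.05 held for 588 genes in edgeR, 1175 in DESeq2 and 1192 in limma-voom. Interaction calls, 29 as reported, became 165 with DESeq2, 517 with limma-voom, 3372 with library totals (22 and 3350; median of all genes -0.70), 107 without a filter, 3 with thinned counts, 17 with cyclic loess and 7 without both muscle libraries numbered 6; the causes were not tested. Liver against muscle in wild type, 3607 as reported, became 1875 with at least 50 counts in 8 libraries, with 3958 genes tested. The 22 liver lists became 0 with an estimated correlation and 12 with cyclic loess (9 higher, 3 lower; 11 of the 22 kept, with ribosomal and mitochondrially encoded genes turned to a negative sign), and the 6 muscle lists 0 with an estimated correlation and 3 with thinned counts. Genes called in both tissues were 0 under each setting run. Named genes were followed over the settings other than leaving out 1 library, the 2-fold minimum and the adjusted p under 0.10. Over these settings 689 results kept direction and side of the threshold, 67 passed where the reported fit did not and 24 no longer passed. Another 1 moved (gck, -0.08 with library totals), and none turned a call.

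The library numbers were not taken to pair the samples, since not every pair correlated above 0.1: deviations of same-numbered libraries correlated above 0.1 in 3 of 8 liver pairs, 6 of 8 muscle pairs, and 0 and 1 of 8 liver and muscle pairs of wild type and knockout, and 2, 5, 0 and 3 of 8 correlated best with their own number, which in muscle hints at something shared by number. With the number as a block the calls were 5 in liver, 2 in muscle (both lower, cpa5 among them at an edgeR adjusted p of 0.0392, with 907 genes at an unadjusted p under 0.05), 8 for the interaction (6 of them among the 29) and 3358 for liver against muscle. The reported fits and the counts over other splits were made without the block. Depth limits the liver fit: with wild-type livers at 1514099 to 2366219 counts, genes near 1 CPM rest on a few counts per wild-type library.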

Other observations

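The tests of the low-abundance genes and of the gene lists against genes of like abundance were chosen after those results were seen. The tests of gys1 and of the correlation between lists were written before.

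Further lists that passed in knockout liver were heat shock, antioxidant, amino acid catabolism, autophagy, cytochrome P450 and acute phase genes. Of these all but the antioxidant list have medians that turn negative with library totals, which put the median of all genes at -0.54. Of 16 heat shock genes 12 were positive (median 0.24, camera adjusted p = 0.0346, or 0.0580 without knockout liver 1), and 3 rose when adjusted over the list alone. Among them the constitutive chaperone hspa8, which can share reads with a near copy, went from 512 ± 125 to 875 ± 148 CPM in 8 of 8 livers (edgeR adjusted p = 0.00833 over the list and 0.0859 over all genes). Antioxidant genes were positive in 29 of 31 cases (median 0.51, camera adjusted p = 0.000531), with the metallothionein mt2 in the other direction (207 ± 127 and 89.2 ± 42.6 CPM, log2 change -1.22, edgeR adjusted p = 0.119). Amino acid catabolism was positive in 34 of 41 cases (median 0.40, camera adjusted p = 0.00102). Autophagy and lysosome genes were positive in 24 of 30 cases (median 0.37, 0.00238), cytochrome P450 and drug metabolism in 28 of 32 (median 0.22, 0.0173) and acute phase and complement in 26 of 31 (median 0.36, 0.00900). With an estimated correlation none of these lists passed (smallest adjusted p = 0.556). With cyclic loess heat shock (0.161), antioxidant (0.0519), cytochrome P450 (0.0531) and acute phase genes (0.725) did not pass, and heat shock genes did not with at least 50 counts in 8 libraries (0.134).

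The glucocorticoid-responsive gene tsc22d3 of the insulin and fasting list rose when adjusted over the list alone, from 44.1 ± 17.8 to 102 ± 49.4 CPM (log2 change 1.21 ± 0.31, 7 of 8 livers; edgeR adjusted p = 0.0192 over the list and 0.0859 over all genes), while that list of 30 did not pass (camera adjusted p = 0.164). In the oocyte and ovary list, ddx4, a germ-cell helicase, fell over the list alone (11.5 ± 8.80 to 4.94 ± 1.24 CPM, 8 of 8 livers; edgeR adjusted p = 0.0275), and the list did not pass (camera adjusted p = 0.767). The other lists that did not pass in liver were skin, cell cycle, endocrine pancreas, unfolded protein response, lymphocytes, B and plasma cells, neutrophils, adipocytes, interferon response, biliary epithelium, intestine, endothelium, fibroblasts, triglyceride synthesis, circadian clock, pigment cells, bile acids, muscle atrophy, and slow and fast muscle fibres, with camera adjusted p from 0.0851 to 0.856.

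Genes of low abundance held a smaller share of the counts in knockout livers. The median log2 change of share was -0.66 over 10389 genes at 1 to 10 CPM (interquartile range 0.75) and -0.05 over 609 genes at 100 CPM or more. The number of reads alone is argued against as the cause. At equal depth knockout livers still had fewer genes with at least 5 counts (exact permutation p = 0.0003108). Other effects that go with deeper libraries cannot be told apart from genotype, since every knockout liver was deeper than every wild-type liver. Signal carried over from muscle libraries is also argued against, since the change was -0.67 in 9631 genes with little expected carry-over. A few abundant genes are not the whole cause, since leaving the 100 most abundant out of the totals left -0.40. The test of gene length is void, as 79.4% of these genes had a length, under the share set for such a test, and the lengths come from another genome build. The shortest genes with a length were at -0.53, which speaks against length as the whole cause for those genes but is not taken as deciding it. Genotype stays open and untested.

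The lists and this abundance trend may be linked in part. Against 10000 lists of genes of like abundance, 14 of the 22 liver lists that passed had medians outside the central 95% (12 higher, 2 lower). The random lists were drawn without regard to correlation between genes. The estimated correlation was 0.555 for the proteasome, 0.613 for oxidative phosphorylation and 0.706 for cholesterol synthesis. Lists of correlated genes can leave that range by chance, so the test cannot decide whether the trend alone accounts for these 14 medians. In muscle the slow fibre list also lay at percentile 100 and did not pass (camera adjusted p = 0.339). Outside lay the proteasome, oxidative phosphorylation and cholesterol lists (percentile 100 each), the TCA cycle (99.8) and gluconeogenesis (99.7), and nerve and glia at 0.65. For 8 lists the median lay inside, with ribosomal proteins at 65.4, plasma proteins at 62.2 and mitochondrially encoded genes at 82.5, so the trend may account for these. For gys1 the percentile was 12.8 among the 1000 genes nearest in abundance, whose median change was -0.00. The median trend thus gives about no change at this abundance, while single genes of like abundance spread widely enough that 12.8% lay as low as gys1.

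A hypothesis was that pentose phosphate and fatty acid synthesis genes rise and fall together between livers of 1 genotype, since the oxidative pathway supplies NADPH for fatty acid synthesis. The list means correlated with Pearson r = 0.95 in knockout livers (n = 8, exact permutation p = 0.000595, adjusted 0.00119 over 2 tests). Spearman rho was 0.86 (exact permutation p = 0.0107, adjusted 0.0214), and r was 0.81 without the 2 livers farthest from the median. In wild-type livers r was 0.80 (n = 8, exact permutation p = 0.0184, adjusted 0.0184) and rho 0.71 (exact p = 0.0576, adjusted 0.0576), and r was 0.30 without the 2 farthest livers, so there the relation rests on those livers. The hypothesis covered both genotypes and so cannot be decided, since in wild type rho was 0.71 with an exact permutation p of 0.0576. Both list means tended to fall with library number in both genotypes. From liver 1 to liver 8 the pentose phosphate mean went from 6.30 to 4.15 log2 CPM in knockout and from 4.88 to 4.17 in wild type. The fatty acid synthesis mean went from 7.29 to 5.05 and from 6.30 to 5.17. Anything that goes with library number is therefore not separated from a link between the lists. No other pair of lists was correlated, so a relation particular to these 2 lists is not shown. Whether the correlation differs between genotypes was not tested.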
